A study of Caenorhabditis elegans with 4 samples.

How the data were processed

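The study measured binding of GFP-tagged UNC-62 by ChIP-seq in L4 hermaphrodites of 1 strain, with 2 ChIP and 2 input samples. Per the labels' protocols, synchronized worms were fixed with formaldehyde, lysed and sonicated, part of the extract was kept as input, and the rest was precipitated with anti-GFP antibodies. Per the file headers, peaks were placed on WormBase WS220, and the source field of the files names PeakSeq as the peak caller. PeakSeq compares ChIP with control reads, so each deposited peak already reflects an input comparison. The aligner, the number of reads, the scaling of input to ChIP, the threshold and the way the list for the whole series was made are not given in the sources used here.

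The authors deposited 3 peak lists, 1 per ChIP sample and 1 for the whole series, in which each peak has a start, an end and a significance value treated here as a q-value. All deposited q-values lay under 0.001, the highest being 9.99e-04 in replicate 1. That these are q-values was read from the values: multiplied by the number in the peak's name, the value never fell from 1 peak to the next in any list, while the value itself fell 323 times in the series list, as for p-values ranked and then multiplied by a Benjamini-Hochberg factor. Peak numbers ran to 906 in the series list, with 6 numbers not present in it. The inputs had no peak list of their own among the files used here. Read depth is unknown, so no counting interval could be put on any peak's strength, and a q-value depends on depth as well as on binding.

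Lists were read with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Coordinates are 1-based, as deposited. Peaks were counted as shared with an overlap of at least 1 bp. Overlap of the replicate lists was tested against 10000 placements of the replicate 1 peaks at uniform positions on their own chromosome. Peak strength was compared as −log10 q, with Pearson and Spearman correlations and differences of medians tested by 100000 permutations, two-sided. Leaving out the 5 pairs farthest from the median was chosen after the data were seen. Counts per chromosome were tested against length with an exact binomial test, two-sided, with Benjamini-Hochberg adjustment over the 6 chromosomes of a list and a threshold of 0.05. Shares carry 95% Clopper-Pearson intervals, which treat peaks as independent, as do the binomial and Fisher's exact tests. The length of a chromosome was the largest coordinate in any of the 3 lists, since the file headers give no lengths. The autosomes were divided into 3 parts of equal length to count central peaks.

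Apart from the exceptions given below, the regions named in the text were fixed by a rule before the data were examined. The rule took the 15 peaks of the series list with the lowest q. It also took the 20 peaks with the lowest q among those overlapping both replicate lists, which made 22 in all. The rule was written for the genes assigned to these peaks, and positions are given in their place. Peaks without a replicate counterpart and peaks absent from the series list were named after their values were seen. The regions with at least 4 series peaks named under the other observations were not part of the rule set in advance. The overlap test and the chromosome test were checked on simulated lists. With 40 shared peaks planted in each of 50 simulated pairs of lists the size of the replicates, the count exceeded the planted number by at most 1, and 0 of 50 unrelated pairs gave a permutation p under 0.05. With the rate on X doubled in 100 simulated lists of 900 peaks, X was called in 100 of them, and 4 of 100 uniform lists gave any call. The simulated peaks were independent of each other, so the checks do not cover lists whose peaks lie in groups. The chromosome test was not checked on lists as short as those of the replicates.

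Alternatives set before the data were examined were other definitions of overlap, the stronger peaks of each list, other random placements, each replicate list in place of the series list, series peaks with a replicate counterpart, q without the log, and expected shares from the number of protein-coding genes per chromosome. Gene counts were taken from an NCBI RefSeq table of assembly WBcel235. That table is of another build than the peaks, so its coordinates were not used. Tests planned on neighbouring genes, gene groups, gene parts, non-coding RNA genes, sequence motifs and the loci carried by the transgene need a WS220 annotation or sequence and were not run.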

Results

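UNC-62 is the Caenorhabditis elegans member of the Meis/Homothorax family, homeodomain transcription factors of the TALE class that bind DNA with Hox and PBC partners. The experiment asked where UNC-62 is bound in the genome of L4 hermaphrodites, the last larval stage before adulthood. Worms of strain OP600, which carry an integrated unc-62 transgene with a GFP and FLAG tag, were grown at 20 degrees Celsius, and chromatin bound by the tagged protein was collected with an anti-GFP antibody and sequenced (ChIP-seq). The series holds 2 ChIP samples and 2 input samples of total chromatin. The values analysed were 3 lists of peaks: 113 peaks for ChIP replicate 1, 174 for ChIP replicate 2 and 900 in a list for the whole series, all placed on the WormBase WS220 genome. Each peak carried a position and a q-value, and no read count or height, so the sequencing depth behind a peak is unknown. The peaks had a median width of 382 bp in replicate 1, 434 bp in replicate 2 and 309 bp in the series list. They covered 50.1 kb, 86.2 kb and 324.0 kb of the genome, respectively. No peak overlapped another peak of its own list. Regions are named below by their WS220 position, since no gene annotation of that build was used here.

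The first comparison asked whether the same regions were bound in both ChIP replicates. Of the 113 peaks of replicate 1, 75 overlapped a peak of replicate 2, which was 66.4% (95% exact interval 56.9 to 75%). The same 75 pairs made up 43.1% of the 174 peaks of replicate 2 (35.6 to 50.8%). Every overlapping peak had a single partner, and the midpoints of partners lay a median of 34.5 bp apart, within 100 bp in 63 of the 75 pairs. The 75 regions were spread over all 6 chromosomes, with 23 on X, 18 on III, 11 on II, 10 on IV, 8 on V and 5 on I. When the replicate 1 peaks were placed at random on their chromosomes 10000 times, a mean of 0.223 and at most 4 of them overlapped a replicate 2 peak (one-sided permutation p = 0.0001, the smallest these placements can give). When they were instead drawn at random from the series peaks, a mean of 21.5 were shared (permutation p = 0.0001). These draws were not matched on q, and 692 of the 900 series peaks overlapped neither replicate list. They therefore do not show whether replicate peaks are shared more often than series peaks of like strength. Whether the 2 replicates came from separate worm cultures is not stated, so these tests describe the 2 libraries only.

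The strength of the shared peaks was related between the replicates. Over the 75 pairs, −log10 q had a Pearson r of 0.847 and a Spearman rho of 0.644 (two-sided permutation p = 1e-05 for each, the smallest possible with 100000 permutations); peaks within a library are not independent replicates. The strongest peaks carried part of the Pearson value, which was 0.718 without the 2 pairs farthest from the median of replicate 1 and 0.602 without the 5 farthest (permutation p = 1e-05 for each). On q without the log r was 0.318 (permutation p = 0.00629). Of the 75 pairs, 51 had a lower q in replicate 2 and 51 were wider in replicate 2. Of the 20 strongest peaks of each list, 19 in replicate 1 and 18 in replicate 2 were shared. The 38 peaks found in replicate 1 alone had a median q of 4.09e-04, against 3.37e-05 for its shared peaks (difference in median −log10 q 1.08, permutation p = 0.00022). The 99 peaks of replicate 2 alone had a median q of 1.59e-04, against 5.55e-06 for its shared peaks (difference 1.46, permutation p = 1e-05).

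**Figure D1:**
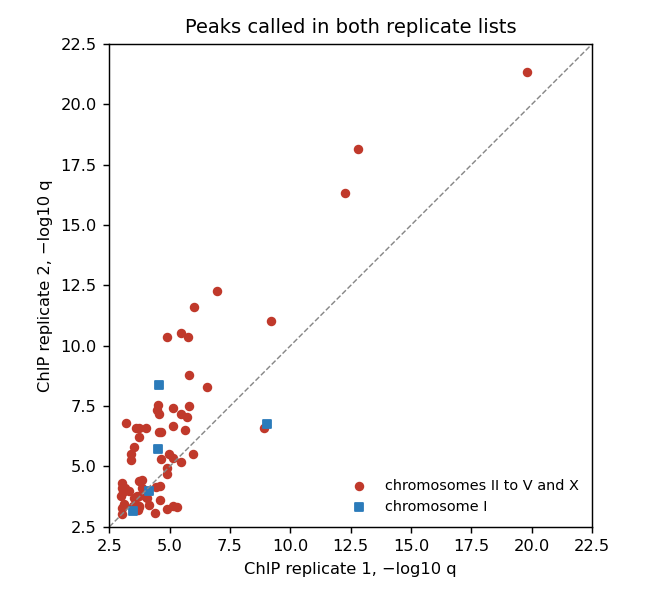
Each point is 1 of the 75 regions called in both replicate lists, with −log10 q in ChIP replicate 1 on the x axis and in ChIP replicate 2 on the y axis; squares are the 5 regions on chromosome I and the dashed line marks equal values. In 51 of the 75 regions q was lower in replicate 2, above the line, and 3 regions stand apart at the upper right.

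The lowest q of the series list belonged to a peak of 1897 bp on chromosome IV at 14032567 to 14034463, with q = 2.95e-34 in that list, q = 1.59e-13 in replicate 1 and q = 7.26e-19 in replicate 2. It was ranked 2 in each replicate. The region ranked 1 in both replicates lay on chromosome V, where the series list held its widest peak, 5585 bp from 4503531 to 4509115 with q = 4.85e-33. The replicate peaks inside it were narrower and nearly coincident, at 4506643 to 4508528 in replicate 1 (q = 1.56e-20) and 4506581 to 4508639 in replicate 2 (q = 4.59e-22). A further strong peak lay a few kilobases to its left, at 4498926 to 4500021, and was ranked 4 and 6 in the replicates. Loci carried by the transgene are present in extra copies in this strain. Whether any region named here is such a locus was not tested. On chromosome III the peak at 8801303 to 8802325 was ranked 3 in every list (q = 1.81e-31 in the series list, 5.66e-13 in replicate 1 and 4.88e-17 in replicate 2). A second peak at 8799815 to 8800885 lay beside it and was also called in both replicates.

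The remaining strong regions of chromosome III were called in both replicates at 4281889 to 4282553, 12612310 to 12612885, 8417145 to 8417929 and 1924776 to 1925689, with series q from 1.05e-21 to 6.10e-16. Chromosome X held strong peaks at 6740749 to 6742483, 16929435 to 16931013 and 11093836 to 11094325, with series q from 2.04e-21 to 7.31e-18, each also called in both replicates. The peak at 6740749 was 1735 bp wide in the series list and held 2 separate peaks of replicate 2. Chromosome V had 1 more such region at 11531873 to 11532667 (q = 7.27e-19), and chromosome IV 1 more at 13695603 to 13696331 (q = 6.66e-16). On chromosome II the strongest series peaks called in both replicates were at 11634901 to 11636080 (q = 8.14e-17) and 10850902 to 10851469 (q = 1.68e-15).

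Chromosome I held 6 of the 22 regions named by the rule set in advance. A trio of peaks lay within 5.38 kb at 5311577 to 5312160, 5312773 to 5313604 and 5315940 to 5316954. The first 2 were called in both replicates and the last in replicate 2 only. The peak at 9381032 to 9382027 had q = 2.77e-27 in the series list, the fourth lowest, but q = 2.72e-05 in replicate 1, where it was ranked 41, and q = 4.17e-09 in replicate 2, where it was ranked 11. The peak at 4172007 to 4172565 was ranked 18 in the series list, 53 in replicate 1 and 91 in replicate 2. The peak at 7474780 to 7475814 was called in replicate 2 only. Of the 15 strongest series peaks, 13 were in both replicate lists and 2 in replicate 2 alone, and those 2 were on chromosome I.

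**Figure D2:**
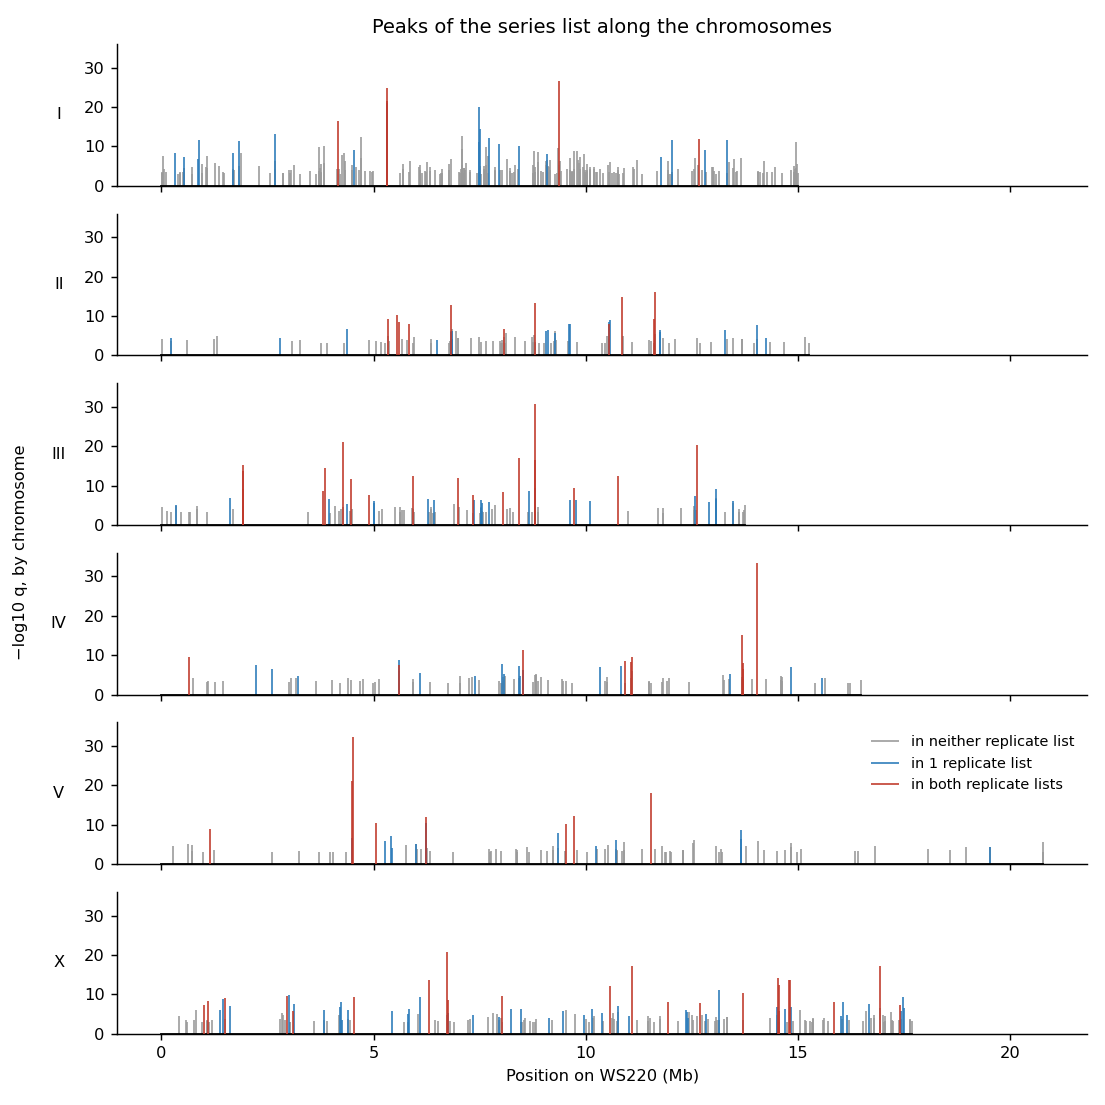
Each vertical line is 1 of the 900 peaks of the series list at its WS220 position in megabases (x axis), with its −log10 q as height (y axis, 1 panel per chromosome); red peaks overlapped both replicate lists, blue peaks 1 list and grey peaks none. The tallest lines, on chromosomes IV, V and III, were in both replicate lists, and the unmatched grey peaks reached higher on chromosome I than on the other chromosomes.

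The next comparison asked how the series list related to the replicate lists. It contained nearly all replicate peaks: 112 of 113 from replicate 1 (99.1%, exact interval 95.2 to 100.0%) and 173 of 174 from replicate 2 (99.4%, 96.8 to 100.0%). The peaks absent from it were at X 15564279 to 15564527 for replicate 1 and IV 2708536 to 2708921 for replicate 2. In the other direction, 208 of the 900 series peaks overlapped a replicate peak (23.1%, 20.4 to 26%). Of these, 75 overlapped both lists, 37 replicate 1 alone and 96 replicate 2 alone. The other 692 series peaks had no counterpart in either replicate list.

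Series peaks with a replicate counterpart were stronger and wider than those without. Their median q was 2.19e-08 against 1.72e-04, a difference of 3.90 in median −log10 q, and their median width was 500.5 bp against 271 bp (two-sided permutation p = 1e-05 for each difference). All 101 series peaks narrower than 100 bp were among the 692 without a counterpart. Of the 100 strongest series peaks 87 had a counterpart, of the next 100 it was 67, and in each of the weakest 2 groups of 100 it was 0. The same site had the lower q in the series list in 112 of 112 pairs with replicate 1 and in 172 of 173 pairs with replicate 2, with a median gain in −log10 q of 4.55 and 3.93. The replicate peaks are not independent of the series list if that list was called from the same reads, which is not stated.

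The share of series peaks with a counterpart was lowest on chromosome I. There 25 of 276 peaks had one (9.06%, exact interval 5.95 to 13.1%), against 183 of 624 on the other chromosomes (29.3%, 25.8 to 33.1%; odds ratio 0.240, Fisher's exact p = 3.08e-12, two-sided). The other chromosomes ranged from 20.2% on V to 37.5% on III. Among the 100 strongest series peaks, 68 of 68 on the other chromosomes and 19 of 32 on chromosome I had a counterpart. The 25 strongest peaks without one were all on chromosome I, the first at 7079186 to 7080206 with q = 2.05e-13. The strongest such peak elsewhere was at III 13067939 to 13068663 with q = 1.61e-07, ranked 151.

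**Figure D3:**
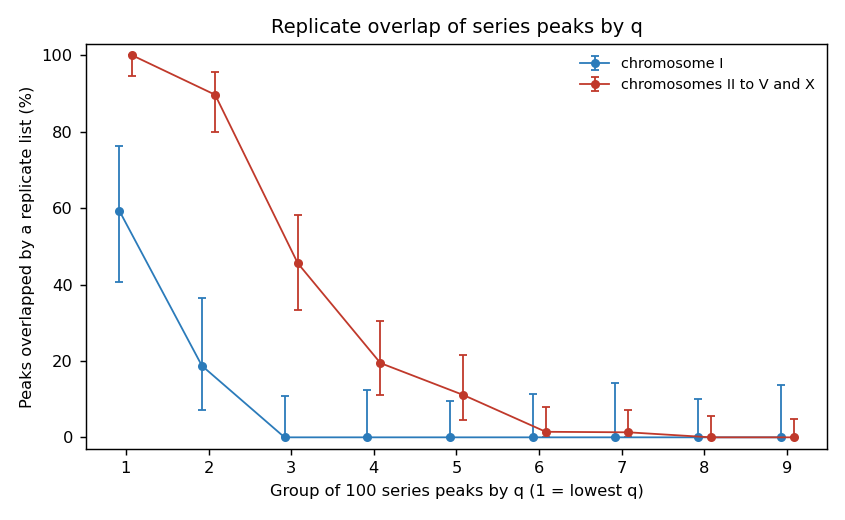
The 900 series peaks were ordered by q and divided into 9 groups of 100 (x axis, group 1 has the lowest q), and the y axis gives the percentage of each group's peaks overlapped by a replicate list, for chromosome I and for the other chromosomes, with 95% exact binomial intervals. In the first group 100% of the peaks of the other chromosomes were matched and 59.4% of those on chromosome I.

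The distribution of peaks over chromosomes was compared with chromosome length. In both replicate lists X held more peaks than its length predicts: 38 of 113 in replicate 1 (33.6%, exact interval 25 to 43.1%) and 51 of 174 in replicate 2 (29.3%, 22.7 to 36.7%), against 17.9% of the length. The ratios of observed to expected peaks were 1.88 and 1.64 (exact binomial test, adjusted p = 3.68e-04 and 0.00131 over the 6 chromosomes). Chromosome V held fewer in both, with 8.85% and 10.9% of the peaks against 21% of the length (ratios 0.421 and 0.520, exact binomial adjusted p = 0.00223 and 0.00221). Chromosome III passed the test in replicate 1 alone, with a ratio of 1.72 (exact binomial adjusted p = 0.00796). In replicate 2 its ratio was 1.36 (exact binomial adjusted p = 0.124), and the difference between the lists was not tested.

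In the series list chromosome I held 276 of the 900 peaks (30.7%, 27.7 to 33.8%), 2.02 times the number its length predicts (exact binomial adjusted p = 7.63e-31). In the replicate lists the same chromosome had ratios of 0.467 (exact binomial adjusted p = 0.0189) and 0.835 (exact binomial adjusted p = 0.478), so the direction of this result depended on the list. Chromosome V was below expectation in the series list as well, at 0.550 (exact binomial adjusted p = 3.71e-13), and chromosome IV was at 0.714 (exact binomial adjusted p = 1.59e-04), with ratios nearly as low in the shorter replicate lists, 0.744 and 0.793, where it was not called (exact binomial adjusted p = 0.308 and 0.394). X had a ratio of 1.14 that missed the threshold (exact binomial adjusted p = 0.0564). Chromosomes II and III were not called either, at 0.843 and 0.895 (exact binomial adjusted p = 0.0564 and 0.228). Without chromosome I the ratio of X was 1.40 and that of V 0.673 (exact binomial adjusted p = 3.24e-06 for each), while IV was at 0.873 (exact binomial adjusted p = 0.217). Lengths were taken as the largest coordinate in any list, so a chromosome whose end holds no peak is counted as shorter than it is.

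**Figure D4:**
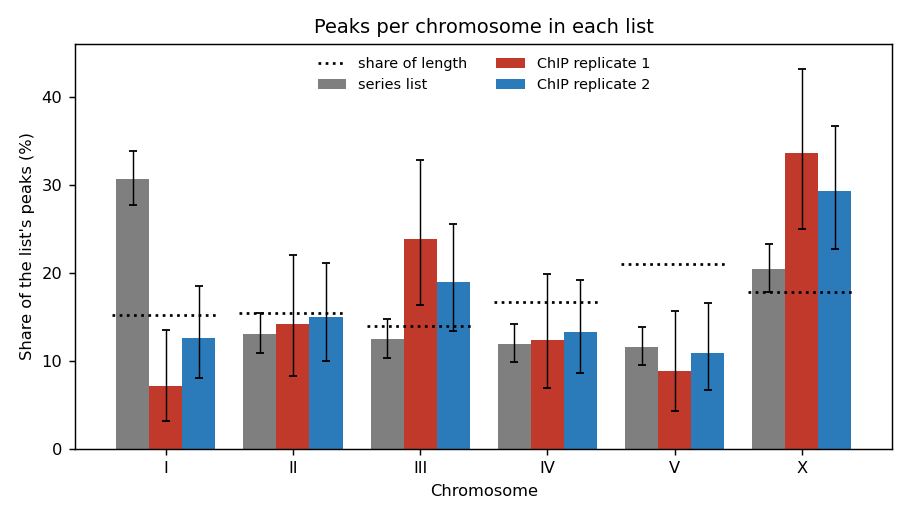
Bars give the percentage of each list's peaks (y axis) on each chromosome (x axis) for the series list and the 2 ChIP replicate lists, with 95% exact binomial intervals, and dotted lines give each chromosome's share of the length. X lies above its dotted line in both replicate lists, V lies below in all 3 lists, and chromosome I stands at 30.7% in the series list against 7.08% and 12.6% in the replicates.

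On the autosomes peaks were more frequent in the central part, where C. elegans autosomes carry their gene-dense clusters, than in the arms. The central 33.3% of the length held 340 of the 716 autosomal series peaks (47.5%, exact interval 43.8 to 51.2%; exact binomial p = 5.07e-15). The share was 49.3% in replicate 1 (37 of 75, exact binomial p = 0.00456) and 43.9% in replicate 2 (54 of 123, exact binomial p = 0.0164). In the series list each autosome lay above 33.3%, from 43.8% on I to 55.6% on II. X showed no such excess: 61 of 184 series peaks were central (33.2%, 26.4 to 40.5%; exact binomial p = 1). In the replicate lists the central share on X was 31.6% (12 of 38) and 27.5% (14 of 51).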

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

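Leaving out chromosome I, and counting counterparts from 1 replicate list alone, were alternatives chosen after the data were seen. Of 78 values recomputed under an alternative, 51 kept their direction and their side of the threshold (or stayed within their interval), among them all 5 of the central share, all 6 of the ratio of chromosome V and all 8 of the differences between peaks with and without a counterpart. Another 9 changed direction, each of them a ratio of observed to expected peaks on chromosome I, II or III. With the stronger peaks of each list, 36 replicate 1 peaks were shared, out of fewer peaks compared, and 100% of both replicates' peaks were in the series list. With midpoints required within 100 bp these shares were 89.4% and 89.1%. The share of series peaks with a counterpart was 29.3% without chromosome I, and 12.4% to 19% from 1 replicate list alone. The ratio of observed to expected peaks on chromosome I was 0.467 to 0.835 in the single replicate lists and 0.793 among series peaks with a counterpart. Series peaks with a counterpart largely repeat the replicate peaks, so their ratios here and below are no separate check. X rose to 1.64 to 1.88 in the replicate lists, 1.72 among peaks with a counterpart, 1.5 against gene counts and 1.40 without chromosome I, and passed the threshold in each of these. In the stronger peaks of the series list X was at 1.16 and was not called (exact binomial adjusted p = 0.181). Chromosome III was at 0.895 in the series list and at 0.941 against gene counts, not called in either. It was called at 1.72 in replicate 1 and at 1.45 among peaks with a counterpart. It was not called at 1.36 in replicate 2, at 1.02 in the stronger peaks of the series list or at 1.10 without chromosome I. Chromosome IV lost its call in the replicate lists (0.744 to 0.793), among peaks with a counterpart (0.750) and without chromosome I (0.873). Chromosome II was called against gene counts (0.753) and stood at 1.03, not called, without chromosome I. Explanations of the shift on chromosome I are weighed under the other observations; the cause of the remaining shifts was not tested. Alternatives for the tests on neighbouring genes, gene groups, gene parts, non-coding RNA genes, motifs and transgene loci were not run, as those tests were not run. When replicate 1 was drawn at random from the series peaks, without matching on q, a mean of 21.5 peaks were shared, against 75 observed. Pearson's r was 0.318 on q without the log. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no peak list of their own among the files used here. Unknown read depth limits every statement on strength: a peak missing from a replicate list may lie just under its threshold.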

Other observations

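The tests on chromosome I and the comparison of grouped with single peaks were chosen only after the result was seen, and the tests on the spacing of peaks after the lists had been examined but before their own result was seen.

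Peaks of the series list were often grouped. With neighbours at most 5 kb apart counted as 1 region, 266 of the 900 peaks (29.6%) lay in 111 regions of 2 or more peaks, and 29 regions held at least 3. Of the 11 regions with at least 4 series peaks, 6 lay on chromosomes II, III, IV and X, where 17 of their 26 peaks had a counterpart, and 5 lay on chromosome I, where 2 of 22 had one. All 4 series peaks at III 1920996 to 1926794 had a counterpart, with 3 peaks in replicate 1 and 4 in replicate 2. The regions at III 8794648 to 8802325 and X 6736395 to 6749912 each had 3 of 4 series peaks matched, and that at IV 13689353 to 13704435 had 3 of 5. Fewer were matched at II 6822268 to 6826061 (2 of 5) and III 13060951 to 13070757 (2 of 4). On chromosome I, the regions at 9381032 to 9385610 and 1691135 to 1701296 each had 1 of 4 matched, and 0 were matched at 7078669 to 7087543 (6 peaks), 7658033 to 7662338 (4 peaks) and 10097137 to 10104385 (4 peaks). Over all chromosomes 28.9% of the 266 grouped peaks had a counterpart, against 20.7% of the 634 single peaks (odds ratio 1.56, Fisher's exact p = 0.0092, two-sided). Without chromosome I the shares were 40.8% of 157 and 25.5% of 467 (odds ratio 2.01, Fisher's exact p = 3.78e-04). Grouped peaks are neighbours and not independent, so these p-values may be too small. The comparison was not matched on q, with which the share having a counterpart also varied.

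Grouping of this size was not reached by chance placement: uniform placement on each chromosome gave a mean of 99.3 grouped peaks and at most 150 in 10000 draws. Uneven density along chromosomes at scales broader than the local placements does not account for it. Placing each peak within 250 kb to either side of its own position gave a mean of 118.8 and at most 178 (permutation p = 0.0001, the smallest possible). Without chromosome I 157 peaks were grouped against a mean of 63.2. Splitting of broad regions by the caller at gaps under 500 bp is argued against for most neighbours. Of the gaps, 14.8% were this short (exact interval 9.64 to 21.4%), with a median of 1914 bp. Gaps could reach 5 kb by the definition of a region, so splitting at longer gaps stays open. The smallest gap was 203 bp, so closer peaks may have been joined before deposit. Uneven density or mappability within the span of these placements, 250 kb to either side, is smoothed by them and stays open. No biological explanation was tested.

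The series list and the replicate lists disagree on chromosome I, where the series list held 276 peaks and 25 of them had a counterpart. Weaker peaks that only the series list reaches stay open: within groups of 100 peaks of like series q, the share with a counterpart on chromosome I differed from that on the other chromosomes by -21.7 percentage points (permutation p = 0.0001, the smallest possible), but like q need not be like strength if q on chromosome I has another scale. Such a scale is a candidate explanation, for example through the scaling of input to ChIP, which PeakSeq fits by chromosome: at the same sites, the median gain in −log10 q from replicate to series list was larger on chromosome I by 5.76 for replicate 1 (8 sites, permutation p = 0.00447) and by 4.23 for replicate 2 (22 sites, permutation p = 1e-05). Among sites with a replicate q above 1e-06 the differences were 3.99 (7 sites, permutation p = 0.0315) and 4.47 (17 sites, permutation p = 1e-05). Over all matched sites, without this limit on q, chromosome V had the next largest median gains, 7.07 and 5.16, against 10.2 and 7.79 on chromosome I. Chromosome V held fewer series peaks than its length predicts. The gain cannot show which list is off, and too few calls on chromosome I in the replicate lists stays open as well: the upper bound of its share was 13.5% in replicate 1, below its 15.1% of the length, and 18.5% in replicate 2, above it; no biological explanation was tested.

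All 101 peaks under 100 bp were in the series list, the narrowest spanning 2 bp, while the narrowest replicate peaks spanned 117 and 164 bp.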
